A study of Drosophila melanogaster with 4 samples.

How the data were processed

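Chromatin immunoprecipitation with sequencing was performed on whole Drosophila melanogaster embryos of mixed sex, 0 to 24 h old, from a transgenic line that carries the CG8924 protein fused at its C terminus to GFP. Per the labels, an anti-GFP antibody was used and fragments were 200 to 800 bp long. The labels give 1 group with 4 biological replicates, and no second condition, so no groups were compared.

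The authors deposited a peak list for each of the 4 replicates, a list called on pooled reads and a list thresholded for reproducibility between replicates, on the dm6 assembly per the labels. The peak caller and the aligner are not given in the sources used here. Each replicate list and the pooled list hold exactly 30000 peaks, and the thresholded list holds 7842. The deposited signal value of each peak is the authors' own measure of its height, on the scale of its own list, and was used only to rank or describe peaks within a list. The deposited −log10 q-value of each peak was read from the narrowPeak column for it and ranges from 0.432 to 4.25 in the pooled list. The largest q-value in each list of 30000 peaks was 0.276 to 0.376, so these lists include peaks that pass no strict threshold. In the thresholded list every peak has the same value, 4.25. According to the notes deposited with the lists, the pooled and thresholded lists were made from replicates 2, 3 and 4, and replicate 1 is in neither. The pooled list and each replicate list were called against the same control file. The thresholded list is exactly the 7842 highest-signal peaks of the pooled list. Read counts and sequencing depth are unknown from these lists, so no interval that needs depth is given; how well a replicate was sequenced could change the ranks in its list.

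Peaks were placed on 6 chromosome arms of Release 6 (2L, 2R, 3L, 3R, 4 and X), and every peak end lies within the reference arm lengths. Gene annotation was Ensembl release 115, with 18164 genes and 23581 distinct transcription start sites (TSSs) after transposable elements were left out. The summit was the unit of analysis, since 7590 distinct intervals hold the 7842 thresholded summits. Each summit was put in the first of 7 classes that applied, namely promoter (within 500 bp of a TSS), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

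The tests, the 34 gene lists, the 28 motifs and most of the alternatives were fixed before the data were examined. A replicate supported a thresholded peak if one of its own 7842 highest-signal peaks overlapped it by at least 1 bp. Expected support and class shares came from 1000 circular shifts of the peaks along their arms, one-sided for support and two-sided for classes. The expected overlap of each pair of replicates came from 100 shifts of 1 of its lists. Arm shares were compared with the shares of distinct TSSs by two-sided exact binomial tests. A gene had a promoter peak if a thresholded summit lay within 500 bp of one of its TSSs. Gene lists were compared with all other protein-coding genes, and gene biotypes with protein-coding genes, by two-sided Fisher's exact tests. Motifs and all 32896 words of 8 bases were searched on both strands within 50 bp of each summit and in a window of the same width 500 bp to a random side, and compared by two-sided exact McNemar tests. The signal of promoter and other peaks was compared by a two-sided permutation test of the difference in medians with 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method within each of these families, with a threshold of 0.05. Peaks and genes are not biological replicates, so these p-values describe the deposited list. The spread between replicates is given by repeating each result on the 7842 highest-signal peaks of each replicate, as mean ± SD over 4 replicates, a step added after the data were seen.

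Genes and peaks were named by a rule fixed in advance. The rule takes CG8924, the 20 highest-signal thresholded peaks among those supported by all 4 replicates with the gene of the nearest TSS, up to 4 members of each gene list past the threshold and up to 2 of each other list by promoter peak signal, and the 10 words of smallest adjusted p after words shifted by up to 2 bases were merged. Words lower at summits were left out of this ranking of words. List members were matched by current symbol and otherwise by listed synonym. Ald, calypso, Toll and n-syb had no single match, and the roX RNAs are not protein-coding. The annotation groups long non-coding RNAs and microRNAs under 1 ncRNA label, so they were tested together. Symbol patterns brought 4 members of other families into 2 lists, Cp110 and Cp190 into the eggshell and yolk list and Cyp1 and Cyp40 into the cytochrome P450 list. Those lists were kept as fixed and repeated without them.

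The steps were tested on simulated data of the size of the thresholded list, with 7842 summits. Uniformly placed summits gave no class past the threshold and a promoter ratio of 0.947. A planted gene list of 100 genes was called and 0 of 200 random lists were. A planted word ranked 1 of 32896, and 0 words were called where none was planted. These words were sought at uniformly placed summits, so this check does not cover the lower GC content of the real summits. With 40% of summits planted near TSSs, 48.3% were found at promoters, since others fall there by chance, and a planted signal difference of 60 was found as 70.3. With 70.0% of peaks planted as shared, 71.4% were found shared. Alternatives covered the overlap rule, the promoter window, stricter peak sets, leaving out each replicate, the expectation, the gene comparison and the control windows. For peak sets, leaving out a replicate kept the thresholded peaks that the other 3 supported. Their positions and signal still came from the pooled reads of replicates 2, 3 and 4.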

Results

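The binding of the CG8924 protein to the genome was mapped in embryos by pulling down its GFP-tagged form, with 4 biological replicates and no second condition. The thresholded list held 7842 peaks with a median width of 425 bp, covering 2.81 Mb or 2.10% of the 6 chromosome arms. The authors' signal values in it ran from 296 to 12610 with a median of 518. The 4 replicate lists held 30000 peaks each. The pooled reads behind the thresholded list came from replicates 2, 3 and 4, which leaves replicate 1 as a library that played no part in choosing those peaks.

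The binding sites recurred across replicates. All 4 replicates supported 5034 of the 7842 thresholded peaks (64.2%), 1543 were supported by 3 replicates, and 10 by none. Replicate 1, which was not used to make the list, supported 85.9% (95% exact binomial interval 85.1 to 86.6), and replicates 2, 3 and 4 supported 88.5%, 83.9% and 85.8%. Among the 1961 peaks of the highest signal quartile 98.9% were supported by all 4 replicates, against 14.4% in the lowest quartile. The lowest quartile lies near the limit of 7842 peaks taken from each replicate, so much of this difference may come from that limit. Of the thresholded peaks 99.1% to 99.5% overlapped a peak of each full list of 30000. Shifted peaks gave 4.07% to 4.26% on average per replicate, and none of 1000 shifts reached the support by replicate 1 (one-sided permutation p from circular shifts = 0.000999, the smallest that 1000 shifts can give). The reads of replicates 2, 3 and 4 made the list, so their support is built in and is not a test. The pooled and replicate lists were called against the same control, and the thresholded peaks are part of the pooled list. The overlap is thus not independent of that control. Requiring overlap of 50% of both peaks lowered the number supported by all 4 replicates to 2519, and counting summits within 100 bp lowered it to 3919. Taking the 15684 highest-signal peaks of each replicate raised it to 7390 (94.2%).

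Pairs of replicates shared 79.3% ± 1.20 (SD, n = 6 pairs) of their 7842 highest-signal peaks, from 77.4% for replicates 1 and 4 to 80.8% for replicates 3 and 4. Shifted lists shared 4.18% on average. Across the thresholded peaks, which are not independent replicates, the Spearman correlation of ranks between replicates averaged 0.74 and ranged from 0.70 to 0.80.

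The strongest reproducible peak lay in an intron of ush (u-shaped), on 2L from 480425 to 481437 with its summit at 481090, 1402 bp upstream of the nearest TSS, that of cbt (cabut), and ranked 1 in all 4 replicates. The next lay in an intron of CG11050 (2L, 6612373 to 6612980), and the third at the promoter of px (plexus; 2R, 22513967 to 22514584), 202 bp upstream of its TSS. Of the 20 highest-signal peaks supported by all 4 replicates, 13 were at promoters, 5 in introns, 1 in another exon and 1 in intergenic sequence, and none was in a coding exon or a UTR. The promoter peaks among them lay 31 bp upstream of Ugalt, 132 bp upstream of Fkbp14, 125 bp upstream of Art3, 176 bp upstream of the non-coding RNA gene lncRNA:CR44339, 129 bp upstream of CG18549, 170 bp upstream of gish, 156 bp upstream of Gapdh2, 251 bp upstream of CG1888, 153 bp upstream of CG18428 and 233 bp upstream of msi (musashi), with those of CG11309 and CG9147 91 and 23 bp downstream. The intronic ones lay inside Lk6, Trl and CG32772 besides the 2 already given. Trl encodes the GAGA factor, and its intronic peak was on 3L from 14759167 to 14759934. A further peak lay in an exon near lncRNA:CR44619, and the intergenic one lay 11907 bp from the nearest TSS, that of CG13323.

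CG8924 itself (X, 15941077 to 15944449, forward strand) had no thresholded peak within 500 bp of its TSS. The nearest thresholded summit was 3879 bp from that TSS, at 15944956, past the end of the gene. Each replicate list had a summit within 500 bp of the TSS, at rank 5074 in replicate 1, 17527 in replicate 2, 10416 in replicate 3 and 2534 in replicate 4, so that only replicates 1 and 4 placed it among their 7842 highest. Its best rank in the pooled list was 7875.

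CG8924 peaks gathered at promoters and were nearly absent from coding exons. Promoters held 4137 of the 7842 summits, 52.8% against 13.6% ± 0.62 (SD over shifts) expected, a ratio of 3.88. Coding exons held 11 summits, 0.140% against 13.1% expected, and 3′ UTRs held 50, 0.638% against 5.06%. Introns held 31.5% against 39.4%, and intergenic sequence 13.4% against 27.2%. The adjusted p was 0.0028 for each of these 5 classes in the two-sided permutation test by circular shifts, from the smallest p that 1000 shifts can give. The 5′ UTR (permutation adjusted p = 0.119) and other exons (0.541) did not pass. The call on the 5′ UTR depended on the peaks and the window. It was lower than the shifts among the 3921 highest-signal peaks (permutation adjusted p = 0.0117), without replicate 3 or 4 (0.0140 and 0.0210), in replicate 1's own list (0.0047) and with promoters taken as 1000 bp either side of a TSS (0.0023). With 200 bp either side both the 5′ UTR and other exons were higher (permutation adjusted p = 0.0060 and 0.0047). In the replicates' own lists promoters held 52.8% ± 2.42 (SD, n = 4) of summits and coding exons 0.147% ± 0.049.

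**Figure D1:**
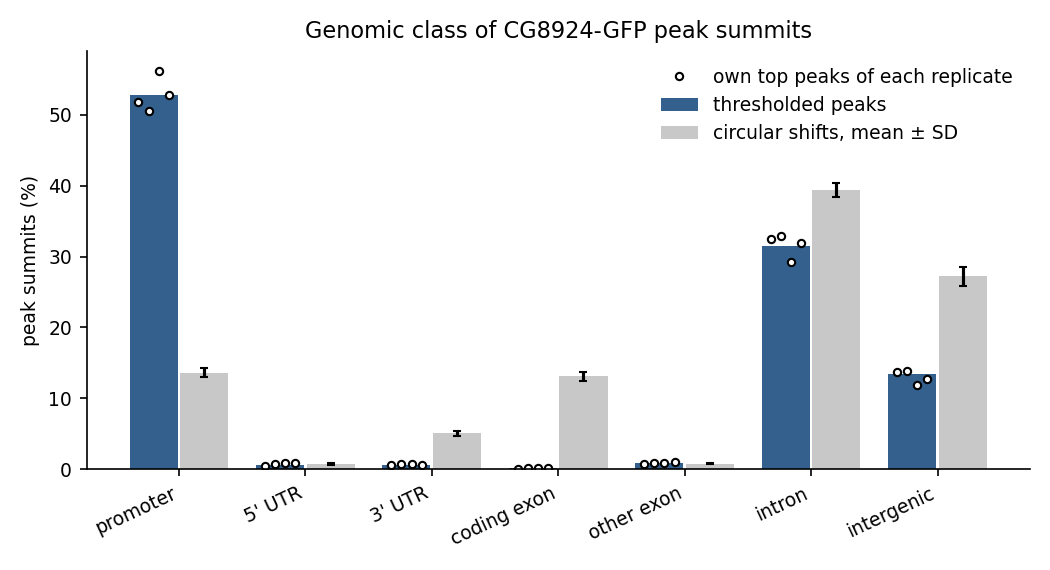
Share of peak summits (%) in each of 7 genomic classes, with blue bars for the 7842 thresholded peaks, grey bars for the mean of 1000 circular shifts with its SD, and open points for the highest-signal peaks of each of the 4 replicates. Promoters hold 52.8% of summits against 13.6% expected, and coding exons 0.140% against 13.1%.

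Peaks were spread over the arms nearly as TSSs are, with modest departures. Arm 3L held 21.8% of peaks (95% exact interval 20.9 to 22.8) against 19.3% of TSSs, and the X 17.9% (17.1 to 18.8) against 16.6%. Arm 2R held 17.7% against 20.6% and the small chromosome 4 held 41 peaks, 0.523% against 0.776%. These 4 arms passed the exact binomial test (adjusted p = 4.2e-08 for 3L, 0.0027 for X, 4.7e-10 for 2R and 0.0124 for 4), while 2L (adjusted p = 0.157) and 3R (adjusted p = 0.894) did not. The test counts each summit as independent, although 7842 summits lie in 7590 distinct intervals, so its p-values and intervals may be too small. The excess on the X was lost among the 3921 highest-signal peaks (exact adjusted p = 0.439), in replicate 4's own list (0.125) and against arm length in place of TSSs (0.423), and its adjusted p over 12 alternatives ran from 0.00033 to 0.439. Chromosome 4 did not pass in the first and second of these (exact adjusted p = 0.0717 and 0.125). Its log2 ratio was -0.68 in the first against -0.57 in all 7842 peaks, so the depletion was no smaller there, and -0.37 in the second. Leaving out 1 replicate gave -0.92 to -0.61 for chromosome 4. Arm 3L was lost against arm length (exact adjusted p = 0.107), where 2L turned higher (0.0120). Against TSSs 2L was lower in the own lists of replicates 1 and 3 (exact adjusted p = 0.0224 and 0.0465).

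Of 13945 protein-coding genes, 4383 (31.4%) had a promoter peak. Of the 34 gene lists, 12 had a higher share than other genes, 5 a lower share and 17 did not pass. No comparison took account of how open or active promoters are. An excess of peaks thus cannot be told apart from general enrichment at such promoters.

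Genes for protein synthesis and turnover and for the cell cycle had a promoter peak more often than other genes. Of 93 cytoplasmic ribosomal protein genes, 70 (75.3%) had a promoter peak against 31.1% of other genes (log2 odds ratio 2.73 ± 0.34 SE, Fisher's exact test, adjusted p = 4.2e-17), with 76.3% ± 0.88 (SD, n = 4) in the replicates' own lists. The highest of their peaks was at RpL34b (3R, 9401125 to 9401607, rank 422 of the thresholded peaks), followed by RpS27, RpLP1 and RpL14 at ranks 514, 614 and 697. Mitochondrial ribosomal protein genes had a peak in 43 of 73 cases (58.9%, exact adjusted p = 8.4e-06), with mRpS10 at rank 8 (3R, 15229274 to 15229785, a peak shared with Art3), mRpS23 at 28, mRpL41 at 57 and mRpL23 at 110. Of 35 cell cycle and DNA replication genes 21 had one (60%, exact adjusted p = 0.0022), led by the mitotic kinase gene Cdk1, Dp, dap and Mcm2 at ranks 983, 1035, 1343 and 1423, a call lost among genes with 1 TSS (0.0884), where the log2 odds ratio was 1.34 against 1.70. Of 32 proteasome subunit genes 20 had one (62.5%, exact adjusted p = 0.0013), led by Rpn13, Rpn3, Rpn11 and Rpn6 at ranks 415, 1370, 1762 and 1956. The call was lost among the peaks supported by all 4 replicates (0.280), among the 3921 highest-signal peaks (0.884) and with any 1 replicate left out (0.0858 to 0.261). The log2 odds ratio fell from 1.84 to 0.91, to 0.35 and to between 0.81 and 1.20 in these, in the same order. In the own lists of all 4 replicates the proteasome list passed (exact adjusted p = 0.0011 to 0.0097). Of 12 glycolysis genes 8 had one (exact adjusted p = 0.0257), among them Gapdh2 at rank 14, Hex-A at 65, Eno at 98 and Ldh at 104, and this call was lost in 12 alternatives, among them the own lists of 3 of the 4 replicates (0.104 to 0.313). Its log2 odds ratio in those 12 was 1.13 to 1.82 against 2.04, so with 12 genes a modest change ended the call. The 84 oxidative phosphorylation genes did not pass (40.5%, exact adjusted p = 0.139) but passed as higher with a 200 bp promoter window (0.0332), and their highest peaks were at ND-ASHI (rank 523) and ND-MWFE (rank 908).

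Genes for chromatin regulators also had a promoter peak more often. Of 18 trithorax group genes 14 had a promoter peak (77.8%, log2 odds ratio 2.82 ± 0.78 SE, exact adjusted p = 0.000296), with brm, the ATPase of the Brahma remodelling complex, at rank 160 (3L, 15982797 to 15983217), Rbbp5 at 1162, Trl at 1779 and fs(1)h at 2090. Of 19 Polycomb group genes 14 had one (73.7%, log2 odds ratio 2.53 ± 0.72 SE, exact adjusted p = 0.000709), with ph-p at rank 30 (X, 2136637 to 2138249), E(z), the histone H3 lysine methyltransferase gene, at 253, Su(z)12 at 1420 and Sfmbt at 1539. Insulator and architectural protein genes had one in 14 of 22 cases (63.6%, exact adjusted p = 0.0055), led by Chro at rank 21 (3L, 22878501 to 22879209), Cp190 at 79, M1BP at 283 and pzg at 1006. Each of these 3 lists passed in the own lists of all 4 replicates, while among genes with 1 TSS the Polycomb and insulator lists no longer passed (exact adjusted p = 0.0785 and 0.0791), with log2 odds ratios of 1.83 against 2.53 and 1.59 against 1.90. Of 16 genes of the BTB zinc-finger list 11 had one (68.8%, exact adjusted p = 0.0058), led by lola at rank 805, Trl at 1779, BtbVII at 1783 and bab2 at 2153, but the call was lost in 11 alternatives, among them the own lists of 3 of the 4 replicates (0.106 to 0.170) and the peaks supported by all 4 (0.505), where the log2 odds ratio was 0.75 against 2.19. The 6 dosage compensation genes did not pass (3 with a peak, exact adjusted p = 0.505), with Clamp at rank 2722 and msl-2 at 5064. The trithorax, insulator and BTB zinc-finger lists share members with a peak, so their calls are not independent. Trl counts in each of them, lolal and psq in the trithorax and BTB lists, and mod(mdg4) in the insulator and BTB lists.

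Among signalling and neural lists the calls were mixed. Of 22 axon guidance genes 17 had a promoter peak (77.3%, log2 odds ratio 2.8 ± 0.71 SE, exact adjusted p = 6.2e-05), led by unc-5, Sema1a, PlexA and Dscam1 at ranks 509, 1129, 1825 and 2024, though in replicate 1's own list the share was 54.5% and did not pass (0.0557). Leaving out 1 replicate moved the log2 odds ratio for axon guidance to between 1.94 and 3.35, and it passed each time. EGFR and FGF pathway genes had one in 17 of 27 cases (63.0%, exact adjusted p = 0.0035), with spi, the main EGFR ligand gene, at rank 213 (2L, 19575329 to 19576331), aos at 249, stumps at 407 and Krn at 467, and the call was lost among the 3921 highest-signal peaks (0.0613), among genes with 1 TSS (0.162) and in a logistic model with TSS number and gene length, with log2 odds ratios of 1.38, 1.59 and 1.08 against 1.87. Notch pathway and E(spl) genes had one in 14 of 24 cases (58.3%, exact adjusted p = 0.0162), led by E(spl)m7-HLH at rank 168, numb at 220, E(spl)m3-HLH at 287 and E(spl)mdelta-HLH at 420, and this call was lost in 10 alternatives, among them the peaks supported by all 4 replicates (0.379) and the own lists of replicates 1 and 3 (0.0591 and 0.142), with log2 odds ratios of 0.86, 1.39 and 1.13 against 1.59. Wnt (52.0%, exact adjusted p = 0.0599), Hedgehog (53.8%, adjusted p = 0.210) and Dpp (31.2%, adjusted p = 1) pathway genes did not pass, with sgg at rank 157 and nkd at 599 for Wnt, dlp at 1134 and ci at 2209 for Hedgehog, and shn at 1986 and tkv at 4098 for Dpp. The Wnt list passed in the own lists of replicates 2, 3 and 4 (exact adjusted p = 0.0084 to 0.0103) and not in that of replicate 1 (0.273). Proneural and neuroblast genes (45.0%, exact adjusted p = 0.352; insc at 1478, da at 2281) and neuronal differentiation genes (23.8%, adjusted p = 0.700; elav at 61, comt at 2351) did not pass either.

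The embryonic patterning and mesoderm lists did not differ detectably from other genes. The share was 33.3% for the homeotic complexes (bcd at rank 2659, lab at 6858), 18.2% for gap and head gap genes (btd at 1708, oc at 2478), 36.8% for pair-rule and segment polarity genes (nkd and ci as above), 18.8% for dorsal-ventral patterning genes (tin at 212, Dr at 4795) and 17.6% for mesoderm and muscle regulators (tin, and Mef2 at 3999), with exact adjusted p from 0.442 to 1. Muscle structure (21.7%; Msp300 at 262, sls at 433), ecdysone response (38.5%; Eip75B at 211, Hr78 at 628), germline (35.7%; piwi at 865, vas at 2827), heat shock (40.9%; Hsp27 at 190, Hsp26 at 1012) and innate immunity genes (20%; cact at 413, imd at 498) also did not pass, with exact adjusted p from 0.210 to 0.824. In a logistic model with TSS number and gene length the neuronal differentiation, muscle structure and mesoderm lists passed as lower, and with peaks anywhere in the gene the ecdysone list passed as higher. The piwi peak had no overlapping peak in replicate 3's list. These lists hold from 11 to 40 genes, so only a large difference could pass.

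In 5 gene lists a promoter peak was rarer than in other genes. Of 179 chemosensory receptor genes 3 had a promoter peak (1.68%, log2 odds ratio -4.56 ± 0.78 SE, exact adjusted p = 1.4e-23), namely Ir60b, Gr63a and Ir31a at ranks 4477, 4694 and 5908. Leaving out 1 replicate moved this log2 odds ratio to between -5.23 and -4.0. Of 70 cuticle protein genes 3 had one (4.29%, exact adjusted p = 2.9e-07), namely Cpr67Fa1, Cpr65Ea and Cpr67Fb at ranks 5986, 6971 and 7763. Of 85 genes in the cytochrome P450 list 6 had one (7.06%, exact adjusted p = 6.9e-07), led by Cyp6u1, Cyp310a1, Cyp317a1 and Cyp9f2 at ranks 325, 2466, 2528 and 2907. In the list of chorion, vitelline and yolk genes 1 of 21 had one (exact adjusted p = 0.0163), and that member, Cp190, is an architectural protein that shares the symbol pattern. The call was lost in 10 alternatives, among them the own lists of replicates 1 and 2 (exact adjusted p = 0.0708 and 0.0646), with log2 odds ratios of -3.46 to -1.66 in the 10 against -2.65, while without Cp190 and Cp110 the count was 0 of 19 (0.0027). None of 111 replication-dependent histone genes had one (exact adjusted p = 1.3e-17). The histone genes are near-identical copies in 1 cluster, so they are not independent genes, and how reads from such copies were placed is not given in the sources used here.

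**Figure D2:**
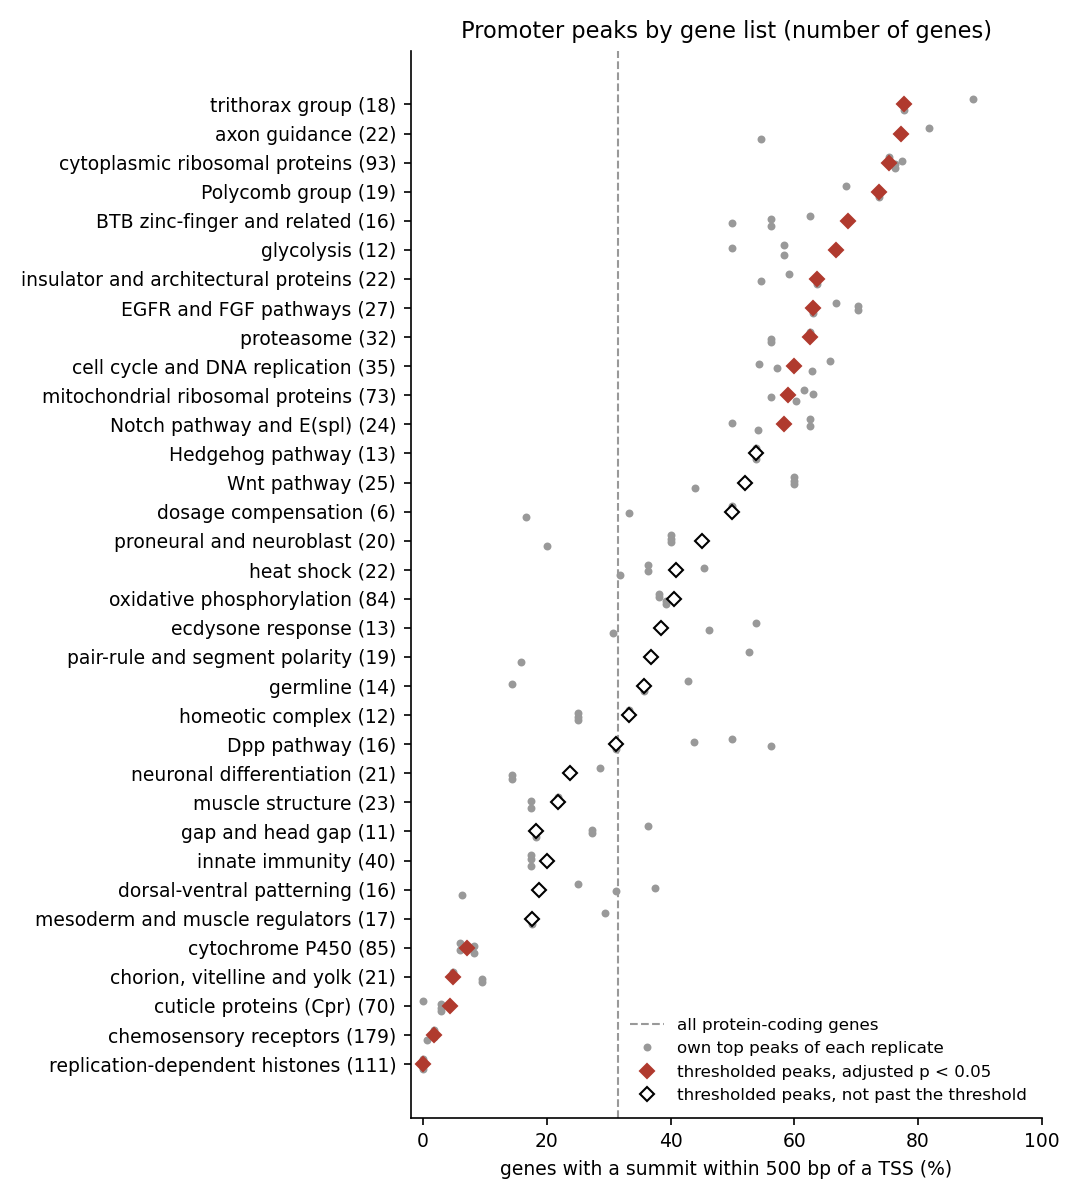
Share of the genes of each list (%) with a thresholded summit within 500 bp of a TSS, where diamonds are the thresholded peaks, filled where the adjusted p is under 0.05, small grey points are the highest-signal peaks of each of the 4 replicates, and the dashed line marks the 31.4% of all protein-coding genes. Trithorax group, axon guidance and cytoplasmic ribosomal protein genes lie above 75%, and chemosensory receptor and histone genes lie under 2%.

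Genes of other biotypes had a promoter peak less often than protein-coding genes. The share was 10.3% of 290 tRNA genes (adjusted p = 7.2e-17), 7.81% of 269 snoRNA genes (adjusted p = 4.3e-20), 10.2% of 3261 other non-coding RNA genes (adjusted p = 4.0e-152) and 4.48% of 268 pseudogenes (adjusted p = 2.4e-27), all by Fisher's exact test. None of 99 rRNA genes had one (exact adjusted p = 1.1e-16), and these are repeated sequences. Of 32 snRNA genes 6 had one (18.8%, exact adjusted p = 0.132), which did not pass, though it did among peaks supported by all 4 replicates (0.0309). In the replicates' own lists the share was 31.0% ± 0.37 (SD, n = 4) for protein-coding genes and 10.2% ± 0.42 for the other non-coding RNA genes.

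Motifs of housekeeping promoters were found at summits more often than 500 bp away. The M1BP motif (GGTCACACT), also known as core promoter motif Ohler 1, was within 50 bp of 97 summits (1.24%) and in 5 control windows (0.0638%; exact McNemar test, adjusted p = 2.4e-22). The DREF motif TATCGATA, bound by a regulator of replication and growth genes, was at 2.03% of summits against 0.268% (exact adjusted p = 8.2e-27), the Ohler 7 motif at 5.36% against 2.86% (adjusted p = 7.8e-15), the Ohler 6 motif at 0.536% against 0.0765% (adjusted p = 2.8e-07) and the BEAF-32 core CGATA at 15.6% against 11.8% (adjusted p = 1.2e-11). CGATA lies within TATCGATA, so each window with the DREF motif also counts for BEAF-32, and the 2 results are not independent. The overlap is partial, with CGATA at 1225 summits and in 926 control windows, against 159 and 21 for TATCGATA. In the replicates' own lists DREF was at 2.02% ± 0.12 (SD, n = 4) of summits against 0.319% ± 0.090, and these 5 motifs passed in all 4. Leaving out 1 replicate moved the log2 ratio to between 3.22 and 4.11 for M1BP (4.15 with all 7842 peaks), 2.34 and 3.38 for DREF (2.89) and 2.52 and 3.66 for Ohler 6 (2.71). All 5 also passed against control windows of the same genomic class and GC content, a comparison chosen after the data were seen. DREF was at 0.370% and M1BP at 0.230% of those windows. The windows were not matched for distance to a TSS or for type of promoter, while the median position of promoter summits was 73 bp upstream of the nearest TSS. The comparison thus cannot tell binding at these motifs from promoter type or closeness to a TSS. At the 3705 peaks outside promoters none of the 5 passed (exact adjusted p = 0.125 to 1), but M1BP, DREF and Ohler 6 are rare there. M1BP was at 5 summits and in 0 control windows, DREF at 10 and 6 and Ohler 6 at 7 and 3, too few to tell whether these 3 differ, while BEAF-32 was at 365 and 367 and Ohler 7 at 88 and 100.

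AT-rich motifs were also higher at summits than 500 bp away, with the TATA box at 22.8% against 10.3% (exact adjusted p = 6.7e-96), the homeodomain core TAATTA at 10.4% against 5.64% (adjusted p = 8.2e-27) and ATATATAT at 3.09% against 1.40% (adjusted p = 2.1e-12). None of these 3 passed against windows of the same class and GC content (exact adjusted p = 0.069 for TATA, 0.872 for TAATTA and 0.138 for ATATATAT). The CTCF core was at 0.510% against 0.230% (exact adjusted p = 0.0107), but it was lost with any 1 replicate left out (0.784 to 1) and its ratio turned below 1 among the 3921 highest-signal peaks. It passed in the own lists of replicates 1, 2 and 4 (exact adjusted p = 0.0185, 0.0090 and 0.0315), and against matched windows it was higher (0.510% against 0.102%, adjusted p = 1.2e-05). The Su(Hw) core at 0.268% against 0.102% (exact adjusted p = 0.0450) was lost in 10 alternatives, among them the own lists of replicates 1, 2 and 3 (0.0785 to 0.353) and matched windows (0.458). Lower at summits were the Ttk core GGTCCTG (0.0893% against 0.650%, exact adjusted p = 7.5e-09), CAGGTG (1.99% against 4.20%, adjusted p = 3.4e-15), CACGTG (0.816% against 1.40%, adjusted p = 0.0013) and the CAG repeat (0.395% against 0.944%, adjusted p = 8.3e-05). Of these, CACGTG was lost in 9 alternatives and the CAG repeat in replicate 4's own list and against matched windows. The Ttk core was lost at peaks outside promoters alone, and CAGGTG passed in every alternative that changed the peaks or the windows. The GAGA repeat was lower as well (1.98% against 2.73%, exact adjusted p = 0.0047), but this turned with the control and the replicate. Leaving out 1 replicate made it lower still, with log2 ratios of -1.15 to -0.67 against -0.46. Replicate 1 had it at 1.25% of summits against 2.84% of flanks and replicate 4 at 3.07% against 2.30%, and against matched windows it was higher at summits (1.98% against 0.893%, exact adjusted p = 5.0e-08). The other 13 motifs, among them Zelda, Initiator, GATA, Mef2, Grainyhead, AP-1, Su(H) and Stat92E, did not pass, though some of them did in alternatives, among them the CA repeat, lower in 9 and higher in 2.

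**Figure D3:**
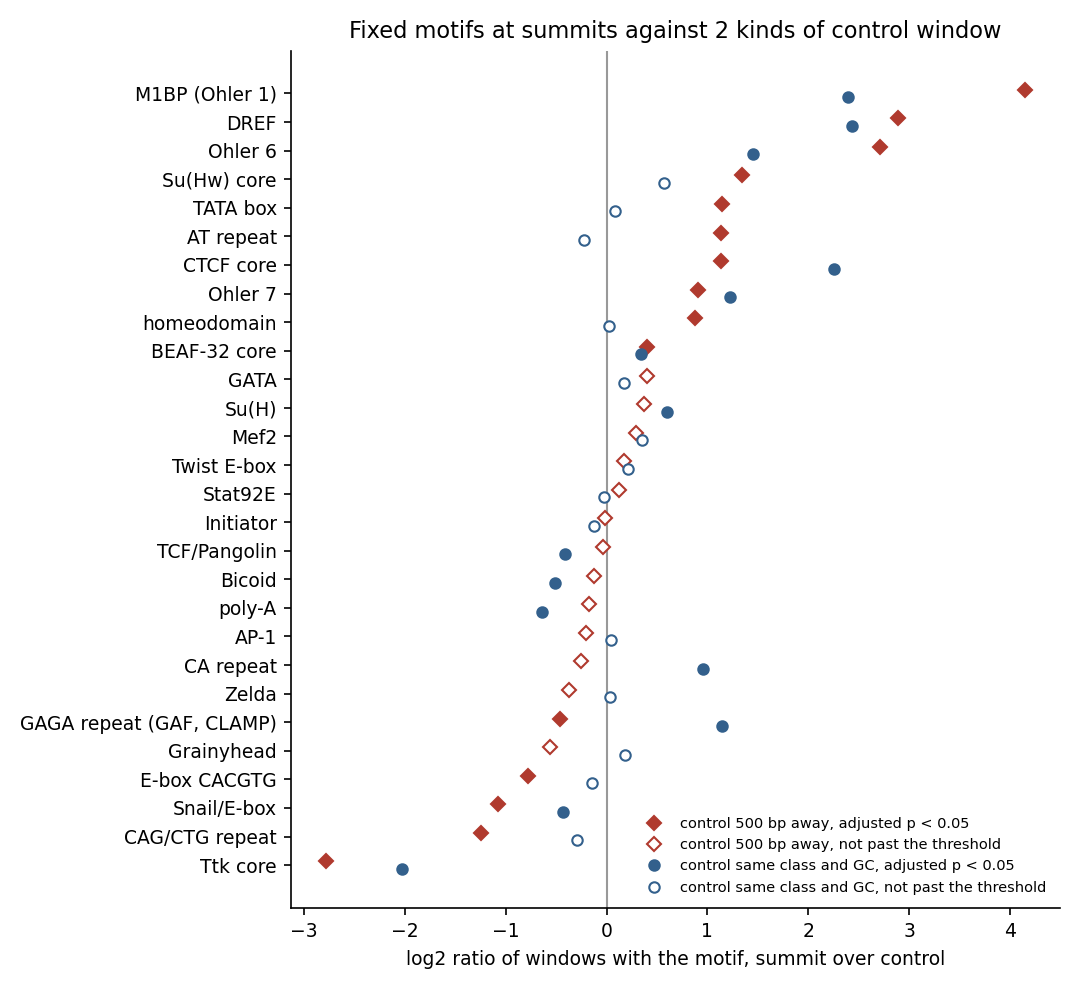
Log2 ratio of the number of summit windows to control windows that hold each of the 28 motifs, with red diamonds for control windows 500 bp away and blue circles for control windows of the same genomic class and GC content, filled where the adjusted p is under 0.05. M1BP and DREF lie above 2 with both controls, while the TATA box, TAATTA and ATATATAT lie near 0 with the matched control.

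Of the 32896 words of 8 bases, 1744 were higher and 2290 lower at summits than 500 bp away. Among the words higher at summits, the 10 of smallest exact adjusted p were all made of A and T, namely ATATTTTA (5.67% of summits against 1.70%, adjusted p = 1.8e-37), AATAATAT, ATATTTAA, TTAAATAA, ATATTAAA, TTTAAAAA, AATAAATA, TAAAATAA, AATATATA and AAAAATAT. Against windows of the same class and GC content, which leave TSS distance and promoter type unmatched, 129 words were higher and 36 lower. The leading ones were then TATCGATA (2.03% against 0.370%, exact adjusted p = 2.1e-18), GAGCGAGA (1.25% against 0.179%, adjusted p = 2.1e-13) and GGTCACAC (1.67% against 0.370%, adjusted p = 7.2e-13). No word in the lists of leading words lay at more than 6.90% of summits.

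Peaks at promoters had a slightly higher signal than other peaks in the thresholded list. The median signal was 538 at 4137 promoter peaks and 499 at 3705 other peaks, a difference of 38.8 (permutation test, p = 1e-05, the smallest that 100000 resamples can give). In the replicates' own lists the difference passed each time, with 14.9, 6.84, 15.3 and 8.56 on the scale of each list (permutation p = 0.0033 in replicate 2 and 1e-05 in the others), and the ratio of medians was 1.09 ± 0.036 (SD, n = 4). Among the 5034 peaks supported by all 4 replicates the difference was -22.9 (permutation p = 0.0597), and among the 3921 highest-signal peaks it was 8.29 (0.551). With peaks kept by the support of the other 3, leaving out replicate 1, 2, 3 or 4 gave -19.7, -27.8, 16.2 and -9.60 (permutation p = 0.118, 0.0145, 0.132 and 0.394). The thresholded list, the replicates' own lists and these subsets are all chosen by signal or by support, which follows signal. The difference depended on which peaks were taken, so whether promoter peaks are stronger in general stays open. Summit position and base composition also moved with signal, as measured after the data were seen. Of the promoter peaks 68.3% (95% exact interval 66.9 to 69.8) lay upstream of the nearest TSS, from 60.7% in the lowest quartile of signal to 81.3% in the highest, where the median position was 132 bp upstream. The sequence within 50 bp of summits held 34.3% G and C on average against 43.3% at 500 bp away and 42.2% over the 6 arms, and 29.7% in the highest quartile of peaks.

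**Figure D4:**
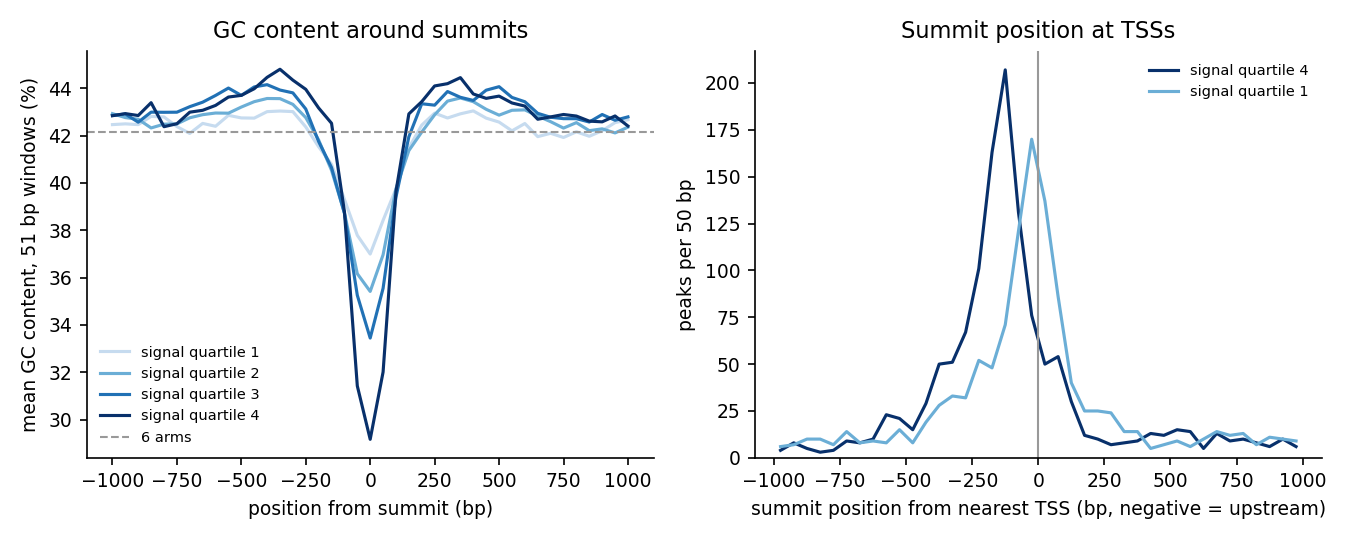
Left, mean GC content (%) in windows of 51 bp against the distance from the summit (bp), by quartile of signal, with the 6 arms as a dashed line, and right, number of peaks per 50 bp against the position of the summit from the nearest TSS (bp, negative upstream) for the highest and lowest quartile. GC content is lowest near the summit in each quartile, and the highest quartile lies farther upstream of the TSS than the lowest.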

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

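The test of replicate 1 below was chosen after the result was seen. With 4 replicates, 83 quantities were examined for 1 replicate standing apart from the other 3, and 16 did so. Chance gives about 1 in 20, or 4.15 of 83. In 12 of the 16 the other 3 replicates had an identical value, which happens easily with counts over short gene lists. The rate of 1 in 20 does not apply to such ties. Those without ties were axon guidance genes, tRNA genes, the DREF motif and GC content 500 bp from summits, no more than the 4.15 given by chance. Replicate 1 had the lowest share of genes with a promoter peak for proneural and neuroblast genes (20% against 40%), Wnt pathway genes (44.0% against 60%), axon guidance genes (54.5% against 77.3% to 81.8%), chemosensory receptors (0.559% against 1.68%) and tRNA genes (7.59% against 12.8% to 13.8%), and the lowest share of summits with the Mef2 motif (0.306% against 0.332%). It had the highest GC content 500 bp from its summits (43.9% against 42.9% to 43.1%). Replicate 4 had the highest share for the homeotic complexes (33.3% against 25%), trithorax group genes (88.9% against 77.8%), mesoderm and muscle regulators (29.4% against 17.6%) and the DREF motif (2.19% against 1.95% to 1.98%), and the lowest for Polycomb group genes (68.4% against 73.7%) and cuticle protein genes (0% against 2.86%). Replicate 2 was highest for innate immunity genes (20% against 17.5%) and the GATA motif (1.61% against 1.45%), and replicate 3 was lowest for snoRNA genes (7.06% against 8.18%).

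Replicate 1 was left out of the authors' pooled and thresholded lists, and it accounts for 7 of these 16 values. For the proneural, Wnt and chemosensory lists and the Mef2 motif among these, the other 3 replicates had an identical value. Binding mostly at other places in replicate 1 is argued against by its support of 85.9% of the thresholded peaks, above the 83.9% of replicate 3. Its pairs shared 77.4% to 79.6% of top peaks, against 78.6% to 80.8% for pairs of the other 3. A difference in part of its peaks is not excluded. Outside the 16 values, its own list also had the lowest GC content at summits (33.0% against 35.3% to 36.1%), the lowest share of summits with the GAGA repeat (1.25% against 2.60% to 3.07%) and the CA repeat (1.90% against 2.89% to 3.93%), and the lowest share of dorsal-ventral genes with a peak (6.25% against 25% to 37.5%). Why it was left out, and whether it differs in depth or antibody yield, stays open, and no biological explanation was tested since the labels give 1 group.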

How the results depend on the processing

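The replicates' own lists, the matched control windows, the genes with 1 TSS, the lists without stray members and the isolated non-coding genes were chosen after the data were seen. The promoter excess passed under every alternative run, with 38.7% of summits at a 200 bp window, 62.0% at 1000 bp and 54.2% to 56.8% leaving out each replicate. The 7842 highest-signal pooled peaks, meant as an alternative, are the thresholded list itself and test nothing. Leaving out a replicate kept the thresholded peaks supported by the other 3, so it also removed weaker peaks. The list itself was still the one made from replicates 2, 3 and 4, so a lost call may reflect fewer peaks and not the replicate. Leaving out a replicate gave 5326 to 5526 supported peaks, 78.8% to 79.9% shared between pairs, 12 gene lists and 13 to 17 motifs past the threshold, 1183 to 1504 words higher at summits, and signal differences from -27.8 to 16.2. The peaks supported by all 4 replicates moved to 2519 with reciprocal overlap of 50%, to 3919 with summits within 100 bp and to 7390 with 15684 peaks per replicate. The count of 2444 for the 3921 highest-signal peaks was against only the 3921 highest of each replicate, so it fell by construction, and against 7842 of each it was 3725. The shared share moved to 61.0% and, for the 1000 top peaks, 81.8%. The signal difference was 8.29 in the 3921 highest-signal peaks and -22.9 in those supported by all 4 replicates, and it passed in each replicate's own list (6.84 to 15.3). All of these sets, like the thresholded list, are chosen by signal or by support that follows it. The signal difference thus depended on which peaks were taken, and whether it holds in general stays open. The log2 ratio for the X was 0.053 in the 3921 highest-signal peaks, 0.062 in replicate 4's list and 0.028 against arm length, where 2L turned to 0.099. The 5′ UTR turned to 0.42 at a 200 bp window, which moves sequence out of the promoter class. The 17 gene lists became 9 among genes with 1 TSS, where fewer genes are tested. Whichever replicate was left out, 5 lists were lost. Their log2 odds ratios stayed at 1.68 to 1.73 for glycolysis (2.04 in the report) and -2.10 to -2.05 for eggshell genes (-2.65), and fell further, to 0.97 to 1.27 for Notch (1.59), 0.81 to 1.20 for the proteasome (1.84) and 0.63 to 0.98 for BTB zinc-finger genes (2.19). The 1744 words became 1055 in replicate 4's list, 2864 with 100 bp each side, 483 words of 6 bases, 765 at promoter peaks, 778 at other peaks and 129 with matched windows. Values past no threshold changed sign in 118 cases. Read depth is unknown, so its part cannot be measured, and apart from the causes named the cause was not tested. No paired analysis was possible because there is only 1 group.

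For single motifs the log2 ratios that turned or moved across the threshold were as follows. In the 3921 highest-signal peaks they were -0.28 for Initiator, -0.40 for the CTCF core, 1.93 for the Su(Hw) core, -0.61 for CACGTG and -1.11 for the CA repeat. Among peaks supported by all 4 replicates they were 0 for the CTCF core, -0.61 for CACGTG and -0.996 for the CA repeat. In replicate 1's list they were -0.83 for Zelda, -0.18 for Initiator, 0.67 for Su(Hw) and -1.0 for the CA repeat. In replicate 2's list they were 0.20 for GAGA, 0.97 for Su(Hw), 0.47 for GATA and 0.34 for Stat92E. In replicate 3's list they were 0.036 for GAGA, 0.76 for CTCF, 0.69 for Su(Hw) and -0.36 for Bicoid. In replicate 4's list they were 0.42 for GAGA, -0.10 for CACGTG, 0.53 for GATA, 0.31 for the CA repeat and -0.24 for the CAG repeat. With 100 bp each side they were -0.036 for GAGA, -0.58 for Zelda, 0.19 for the Twist E-box and -0.32 for Bicoid. With the control on the other side they were 0.67 for CTCF, -0.41 for CACGTG, -0.53 for the CA repeat and -0.24 for poly-A. With the control at 2000 bp they were 0.39 for GAGA, 0.36 for the Twist E-box and -0.41 for TCF/Pangolin. At promoter peaks they were 0.052 for GAGA, 0.83 for CTCF, 0.93 for Su(Hw) and -0.15 for CACGTG. At other peaks they were 0.69 for DREF, 3.46 for M1BP, 1.10 for Ohler 6, -0.0079 for BEAF-32, -0.18 for Ohler 7, 1.11 for CTCF, 2.20 for Su(Hw), -1.47 for Ttk, 1.19 for GATA, -0.85 for Su(H), -0.60 for the CA repeat and -0.43 for poly-A. With matched windows they were 1.14 for GAGA, 0.086 for TATA, 0.57 for Su(Hw), -0.15 for CACGTG, -0.51 for Bicoid, 0.023 for TAATTA, 0.60 for Su(H), -0.42 for TCF/Pangolin, 0.96 for the CA repeat, -0.22 for the AT repeat, -0.64 for poly-A and -0.29 for the CAG repeat. Leaving out each replicate gave -1.15 to -0.67 for GAGA, -0.21 to -0.061 for Initiator, -0.26 to 0.10 for CTCF, 0.74 to 1.78 for Su(Hw), -0.76 to -0.36 for CACGTG, 0.21 to 0.57 for GATA and -1.01 to -0.49 for the CA repeat.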

Other observations

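The tests of core promoter sequence and of the shared control were chosen after the results were seen. Some motifs were more common in lower peaks and others in higher ones, and no test of this was run. The DREF motif lay at 2.55% of summits in the lowest quartile of signal and 0.969% in the highest, and M1BP at 1.84% and 0.306%, while the TATA box lay at 17.6% and 29.7% and TAATTA at 7.85% and 13.8%. Others changed little, with Initiator at 8.98% and 8.16%, Ohler 6 at 0.663% and 0.510% and the Ttk core at 0.102% in both. DREF was at 3.6% of promoter summits and 0.270% of the others, and M1BP at 2.22% and 0.135%.

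Summits were AT-rich, more so in higher peaks (Spearman correlation of GC content with signal -0.29 across the 7842 peaks, which are not independent). GC content rose by more than 8 points within 500 bp of promoter summits, from 35.9% to 44.5%. Core promoter sequence alone is argued against, since summits over 500 bp from any TSS were also lower than their flanks, by -9.51 percentage points (95% interval -9.90 to -9.11). A GC bias of the libraries against the control stays open. Windows of 100 bp with up to 30% GC held a summit in 5.35% of cases at promoters and 0.865% in intergenic sequence, a ratio of 6.19 (95% interval 5.59 to 6.84), which is against such a bias alone choosing where peaks lie, but the bound set beforehand was too narrow, because a bias acting on bound or open promoter DNA could still shift the summit to the AT-rich part, so bias and binding cannot be told apart. No biological explanation was tested.

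Coding exons held summits in 10 of 175285 windows of 100 bp, against 2472 of 528058 in introns, a ratio of 0.0122 (95% interval 0.0065 to 0.0227). GC content of exons is argued against as the whole cause, since at equal GC content the ratio was 0.0233 (95% interval 0.0110 to 0.0490). Distance from TSSs is argued against too, with a ratio of 0.0086 (95% interval 0.0046 to 0.0160) at equal distance. Uneven coverage of the control cannot be told apart from low binding, because the pooled and replicate lists were all called against 1 control file. A low rate of binding in coding sequence remains a hypothesis, and no biological explanation was tested.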
